A study of Prunus persica with 8 samples.

How the data were processed

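RNA was taken from 4 shoot tips of about 4 cm, for each of 4 standard and 4 weeping trees, with 2% PVP added to the lysis buffer, and 50 bp unpaired TruSeq libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The authors deposited 1 table for all libraries. Per the file headers it holds read counts per gene as total exon reads, which include reads that map to several places, and as unique exon reads, which map to 1 place. The reads had been trimmed before mapping, per the file headers. The aligner, the genome build and the annotation are not given in the sources used here, so positions are those of the table's own scaffolds. For all 27864 genes the length equals the whole gene span, so introns count toward it. Start positions were read as counted from 0 and are printed counted from 1, since with that reading the length of 2445 of 3176 genes under 600 bp is a multiple of 3.

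The deposited RPKM values divide total exon reads by that span and by the mapped reads of the library: recomputed from the counts, they matched to rounding error. Mapped reads recovered in this way were 19608717 to 24715162 per library, and 86.8 to 87.5% of them lay in genes. The normalized values in the deposited table are RPKM scaled to sum to 1000000 per library, which makes them TPM values over the gene span. The authors' p-value, its corrected form, the fold of weighted proportions and the score that the test statistic gives come from Baggerley's test, per the file headers. They were used for the overlap only, apart from the fold printed for WEEP. Another 100 columns of other quantities for these libraries and groups were not used.

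Columns were matched to trees by group and tree number. Tree numbers are not shared between the groups, so no pairing was made. The closest pair of libraries, weeping 2 and weeping 3, differed by a chi-square of 16.2 per degree of freedom over genes, well over counting noise, so each library counted as a replicate.

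Total exon reads were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM scaling, the quasi-likelihood F-test on growth habit, and Benjamini-Hochberg adjustment at 0.05 with no fold minimum. The filter left 18520 genes and removed 9344, of which 4564 had no read in any library. The common dispersion was 0.0475. Standard errors of log2 fold changes were taken as the fold change over the square root of F. CPM values use the TMM-scaled library sizes, except for genes switched on or off, where unscaled library totals were used. Principal components were taken from log2 CPM with a prior count of 2. Single values were compared by exact two-sided permutation over all splits of the 8 libraries, whose smallest p is 0.0286. Shares of changed genes were compared by two-sided Fisher exact tests over all tested genes, with 95% intervals, for scaffold 3, for each of scaffolds 1 to 8 other than 3 with Benjamini-Hochberg adjustment, and for genes with midpoints within 2 Mb or 5 Mb of WEEP against the rest of scaffold 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

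On simulated counts with the means, dispersions and library sizes of these data and 200 changed genes, the edgeR test for weeping against standard over 18457 genes recovered 56% of 2-fold and 83% of 4-fold changes, and 6 of its 145 calls were unchanged genes. On the same simulated counts 51 of the 223 DESeq2 calls and 6 of the 142 limma-voom calls were unchanged genes. The simulation drew each gene independently and changed far fewer genes than the 2131 called in the data. Its recovery and false-call shares may therefore not hold for these libraries.

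The design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named WEEP, the 12 genes of smallest adjusted p in each direction whose groups did not overlap, and the 10 changed genes of smallest adjusted p within 1 Mb of WEEP. Since the files do not pair identifiers with gene names, and 0 of the 27864 identifiers matched the RefSeq gene table for assembly NCBIv2, at most 2 identifiers per direction are printed. For the same reason the 30 gene lists that had been fixed could not be matched to the table, and no list test was run. The alternatives fixed in this way were RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), a 2-fold minimum, an adjusted p of 0.01, a 5 Mb window and leaving out each tree. Single-position reads, lane as a model term, lane 6 alone and an offset for gene length were added after seeing the data. So were a 1 Mb window, fold minimums for the scaffold test and further limits for genes switched off or on.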

Results

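Lateral shoot tips of peach (Prunus persica) were profiled by RNA sequencing in 4 trees of standard growth habit and 4 trees of weeping habit, all mature, field-grown members of a segregating F2 population. Weeping trees carry branches that bend downward, whereas standard trees have the usual upright to spreading crown. Each library came from 1 tree, and the labels name the trees as biological replicates. Reads assigned to genes ranged from 17011614 in weeping tree 4 to 21584724 in weeping tree 2. The groups had similar depth, with 18636996 ± 879964 reads in standard trees and 18925619 ± 1989749 in weeping trees (SD, n = 4 each, exact two-sided permutation p = 0.80). Of the 27864 genes listed, 18520 had enough reads to be tested.

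The first question was how WEEP, the gene with which the study is concerned, was expressed in the 8 trees. WEEP encodes a sterile alpha motif (SAM) domain protein. Its transcript was abundant in every standard tree and nearly absent from every weeping tree. The gene (ppa013325m.g, an identifier that is linked to WEEP by knowledge of the study and not by the table itself) lies on scaffold 3 from 15601137 to 15603955, a span of 2819 bp. Standard trees had between 1615 and 1813 reads in it, and the 4 weeping trees had 9, 6, 3 and 7 reads. Its level was 28.3 ± 1.47 RPKM in standard and 0.102 ± 0.0417 RPKM in weeping shoot tips (SD, n = 4 each). All of its reads were placed at a single position of the genome.

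On library-scaled counts the mean was 275-fold higher in standard trees. The fitted log2 fold change, weeping over standard, was -8.09 with a standard error of 0.20, and the adjusted p from edgeR's quasi-likelihood test was 2.2e-07, the smallest of all genes tested. An exact two-sided permutation test of the 8 values gave p = 0.0286, the smallest that 4 against 4 libraries allow. The authors' deposited table lists a fold of -267.9 for the same gene. Within the standard group the highest scaled count was 1.15 times the lowest.

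**Figure D1:**
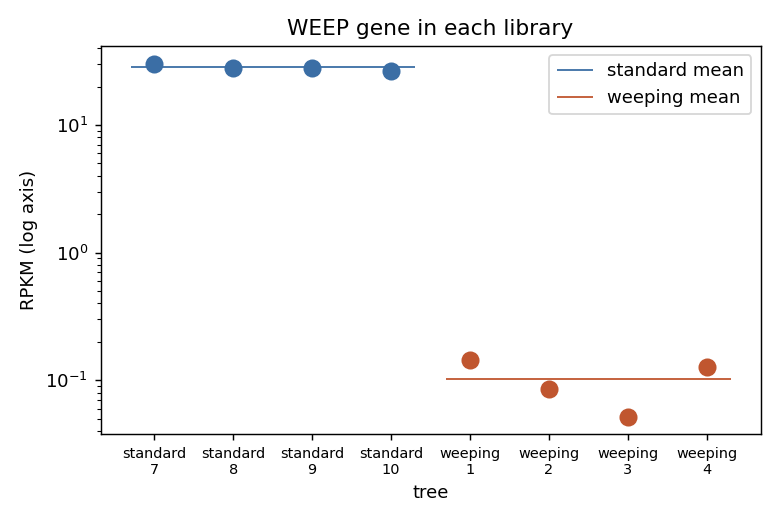
WEEP level in each of the 8 libraries, as RPKM on a log axis, with 1 point per tree and a line at each group's mean. The standard trees have a mean of 28.3 RPKM and the weeping trees a mean of 0.102 RPKM, with no overlap.

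The second question was which other transcripts differed between weeping and standard shoot tips. By edgeR's quasi-likelihood test, 2131 genes passed an adjusted p of 0.05, of which 987 were higher and 1144 lower in weeping trees. Larger changes were mostly decreases: of the 710 genes that also changed at least 2-fold, 537 were lower in weeping trees and 173 higher, and of the 142 that changed at least 4-fold, 127 were lower and 15 higher. The median change was 0.62 on the log2 scale among the genes that rose and -0.95 among those that fell. The balance of all calls was less firm, since more genes were higher than lower with an offset for gene length (1144 against 1037), without standard tree 9 (1760 against 1615) and without weeping tree 3 (226 against 207), while 35.2% were higher within lane 6. The median span was 3267 bp among genes that rose and 2051 bp among those that fell. Among calls of at least 2-fold, decreases outnumbered increases by less with the length offset (467 against 243) and without standard tree 9 (720 against 556). Of all 18520 tested genes, 3461 (18.7%) had every weeping library on one side of every standard library, an arrangement that chance gives for 2.86% of genes.

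The size of this list depended on single trees. Leaving out weeping tree 2 left 20 genes past the threshold, and leaving out standard trees 7, 8 or 10 or weeping trees 1 or 3 left between 255 and 471, whereas leaving out standard tree 9 or weeping tree 4 raised the count to 3375 and 3923. Of the 31 named genes other than WEEP, 16 lost their call without weeping tree 2, at adjusted p of 0.0543 to 0.0779 by edgeR. All 16 kept their direction. They were named for small adjusted p, so they do not speak for the whole list. At an adjusted p of 0.01 the test with all 8 libraries called 9 genes. Weeping trees 3 and 4 were sequenced in lane 8 and the other 6 libraries in lane 6, per the column names. Within lane 6, 4 standard against 2 weeping trees, 1873 genes passed, of which 1292 were among the 2131. Lane 8 held weeping trees only, so it gives no comparison of habit. Between the weeping trees of lane 8 and those of lane 6, 2 libraries each, 3 of 18426 genes passed by edgeR. So few libraries give that test little power.

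The first principal component of log2 CPM held 49.6% of the variance and placed the standard trees between -53.3 and -13.6 and the weeping trees between 0.33 and 67.9. Weeping tree 4, at 0.33, was the weeping library nearest to the standard group, and standard tree 9, at -13.6, was the standard library nearest to the weeping group. The share of reads placed at a single position was 94.4 ± 0.230% in standard and 95.1 ± 0.0692% in weeping trees (SD, n = 4 each, exact two-sided permutation p = 0.0286). The 10 most abundant genes took 5.29 ± 0.171% of the reads in standard and 4.28 ± 0.290% in weeping trees (SD, n = 4 each, exact two-sided permutation p = 0.0286).

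**Figure D2:**
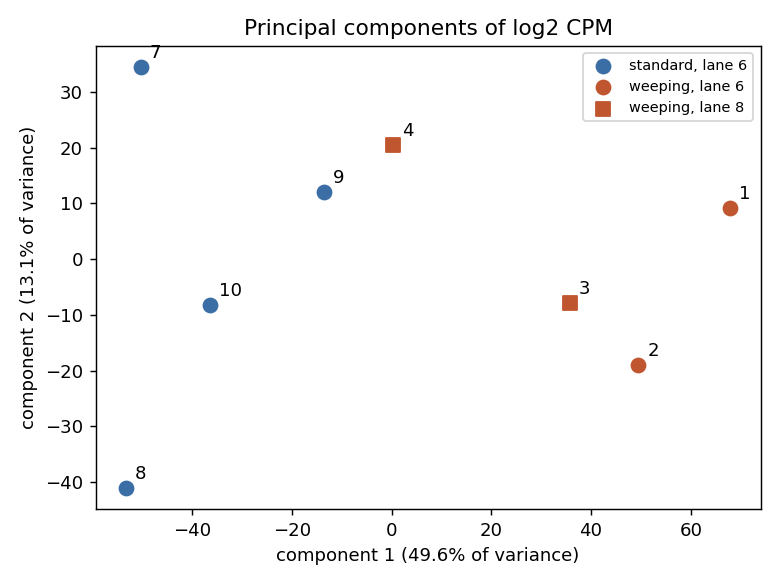
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, labelled by tree number. Colour gives the growth habit and the marker shape the sequencing lane, and component 1 (49.6% of variance) has weeping tree 4 at 0.33 and standard tree 9 at -13.6.

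The rule set for naming genes took the 12 genes of smallest adjusted p in each direction whose groups did not overlap. The table pairs no gene names with its identifiers, so these genes are given by position, with identifiers for few of them. Of the 12 that were higher in weeping trees, 4 lay on scaffold 3, and their log2 fold changes ranged from 0.65 to 2.92. The most significant was ppa019187m.g on scaffold 3 (17891798 to 17896397), which rose from 9.18 ± 0.826 to 69.7 ± 6.76 CPM (counts scaled to library size; SD, n = 4 each), a log2 fold change of 2.92 with a standard error of 0.10 and an adjusted p of 3.6e-06 by edgeR. Of its reads 51.3% were placed at a single position, so part of its level is shared with a similar sequence. With single-position reads alone its log2 fold change was 2.94. The next was ppa002920m.g on scaffold 1 (30614880 to 30620180), which rose from 30.8 ± 2.90 to 62.9 ± 3.74 CPM (SD, n = 4 each; adjusted p = 0.0038 by edgeR).

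Of the 12 genes that were lower in weeping trees, 5 lay on scaffold 3, WEEP among them. After WEEP the most significant was ppa023552m.g on scaffold 3 (16546309 to 16548736), 0.945 Mb from WEEP by midpoints. It fell from 23.0 ± 3.36 to 1.30 ± 0.186 CPM (SD, n = 4 each), a log2 fold change of -4.14 with a standard error of 0.17 and an adjusted p of 6.7e-06 by edgeR. A gene at 18760652 to 18763276 on the same scaffold fell from 22.4 ± 3.24 to 4.93 ± 1.16 CPM, and a gene at 18829367 to 18831840 fell from 7.60 ± 1.43 to 1.65 ± 0.256 (SD, n = 4 each; both adjusted p under the threshold by edgeR).

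The third question was whether changed genes gathered near WEEP, since F2 siblings sorted by habit also differ in the haplotype around the locus. The 4 genes of smallest p were WEEP, ppa019187m.g and ppa023552m.g on scaffold 3 and the gene at 18760652 on the same scaffold, and of the 9 genes with an adjusted p under 0.01, 6 lay on scaffold 3 between 15601137 and 18831840. Of those 6, 4 were lower and 2 higher in weeping trees. Over all calls the excess was small: 254 of 1970 tested genes on scaffold 3 changed (12.9%), against 11.3% elsewhere, an odds ratio of 1.16 (95% interval 1.00 to 1.33, two-sided Fisher exact p = 0.0437). This call was lost without standard tree 8, 9 or 10 or weeping tree 1 or 3 (Fisher exact p = 0.0560 to 0.124), where the odds ratio was 1.12 to 1.34 and, except without standard tree 9, fewer genes were called (255 to 446). It was also lost within lane 6, where the odds ratio was 1.09 (Fisher exact p = 0.286), and with single-position reads, where it was 1.15 (Fisher exact p = 0.0501). The odds ratio was 5.63 among the 20 genes called without weeping tree 2.

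Among the other scaffolds, scaffold 1 had a lower share than the rest, with 420 of 4094 genes (10.3%; odds ratio 0.850, adjusted p = 0.0325 by two-sided Fisher exact tests over 7 scaffolds), and the other 6 did not pass. Within 2 Mb of WEEP 63 of 410 genes changed (15.4%), against 12.2% on the rest of scaffold 3, which did not pass the test (odds ratio 1.30, 95% interval 0.940 to 1.78, two-sided Fisher exact p = 0.0979). Within 1 Mb, a window tested after seeing the data, 38 of 218 genes changed (17.4%), against 12.3% on the rest of the scaffold (odds ratio 1.501, 95% interval 0.9998 to 2.21, two-sided Fisher exact p = 0.0412). Within 5 Mb 142 of 962 genes changed (14.8%), against 11.1% on the rest of the scaffold (odds ratio 1.39, 95% interval 1.05 to 1.82, two-sided Fisher exact p = 0.0185). Genes are not independent replicates, and these intervals treat them as such. WEEP, which defines the windows, counts as a changed gene in each of them and on scaffold 3. No test was run without it, and the 1 Mb result lies close enough to the threshold to depend on it. Of the 38 changed genes within 1 Mb, 18 were higher and 20 lower in weeping trees. The gene at 15418733 to 15420402, 0.183 Mb from WEEP, rose from 1.98 ± 0.722 to 9.01 ± 2.19 CPM, and the gene at 16238709 to 16240073 fell from 16.9 ± 7.43 to 3.17 ± 1.38 (SD, n = 4 each). By edgeR the first lost its call without weeping tree 2 (adjusted p = 0.0549), and the second without standard tree 7 or 8 or weeping tree 2 or 3 (adjusted p = 0.05002 to 0.0608).

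**Figure D3:**
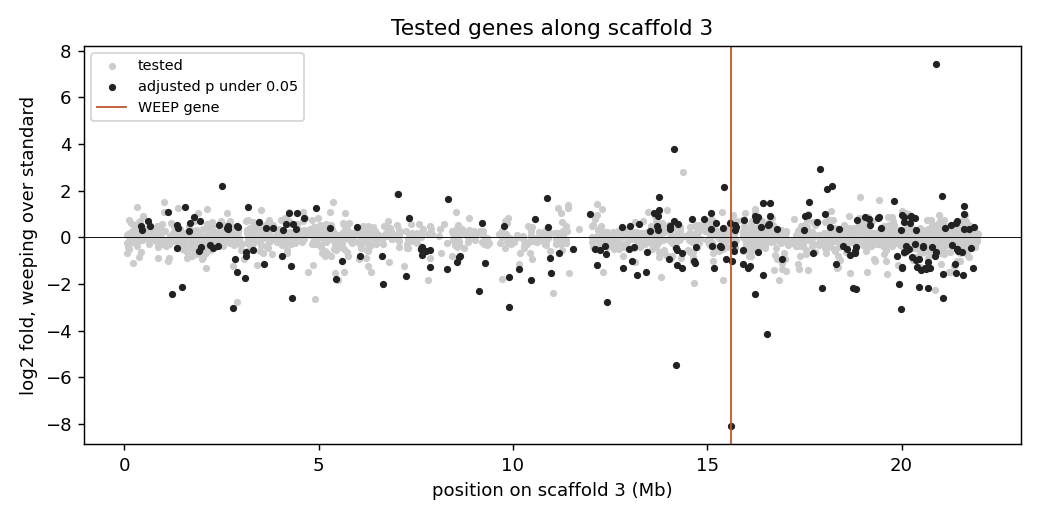
Log2 fold change, weeping over standard, of the 1970 tested genes along scaffold 3, with position in Mb, and the 254 genes past an adjusted p of 0.05 in black. The vertical line marks WEEP, whose point lies at -8.09.

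The authors' deposited table holds a comparison of its own, Baggerley's test on scaled values. At a corrected p of 0.05 it lists 1244 genes, 718 higher and 526 lower in weeping trees. Of these, 960 (77.2%) also passed the edgeR test, all 960 in the same direction. The edgeR list held 1171 genes that the authors' table did not call, with a median absolute log2 fold change of 0.65 against 0.84 for the shared genes. Of the 284 genes called in the authors' table alone, 259 had an unadjusted edgeR p under 0.05.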

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

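The tests of chance and of sequencing lane for the number of changed genes, and of lost reads near WEEP, were chosen after their results had been seen. Of 78 groups of 4 libraries examined for a single outlying value, 1 stood out, where a criterion that chance meets in about 5% of groups would give more. Most of these groups were values of named genes. Those were picked for small adjusted p, which disfavours outlying values, so the low number says little about the libraries. The group that stood out was a gene on scaffold 1 (23400447 to 23402249) in weeping trees. It had 4.38 CPM in weeping tree 4 against 2.29 to 2.62 in the other weeping trees, a gap of 0.843 of the group's range.

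The count of 2131 changed genes was set against chance, lane and gene length. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes, and the highest of the others gave 549. A share of 1 in 35 is the smallest this test can give. It argues against chance assignment of the trees but cannot exclude it. The lane 6 libraries alone gave 1873 genes, and an offset for gene length in each library gave 2181, of which 1829 were among the 2131, which argues against either as the whole source of the count, though the offset turned the balance to more genes higher than lower. That other split exchanged standard tree 9 and weeping tree 4, the libraries nearest to the other group on the first principal component, and kept the other 6 sorted by habit. Growth habit, and any state of the trees that went with it in the field, stay open.

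The excess of changed genes on scaffold 3 was weaker evidence. Among the 2131 genes of smallest p, 2 of the 35 splits, the real one included, had as large an odds ratio for scaffold 3. The highest of the others was 1.22 against the real 1.16, so chance assignment cannot be excluded for this excess. That other split exchanged only standard tree 7 and weeping tree 3 and kept the remaining trees sorted by habit. It therefore holds much of the real contrast and is weak evidence for chance. Reads lost from a haplotype unlike the reference would add decreases. Of the 63 changed genes within 2 Mb of WEEP, 44.4% were lower in weeping trees (exact 95% interval 31.9 to 57.5%). The share was 54.0% among changed genes outside that window, 52.6% within 1 Mb and 52.1% within 5 Mb. With 12.2% of genes changed on the rest of scaffold 3, most of the 63 would be called without any excess. Their balance therefore cannot decide whether reads were lost. A haplotype linked to the weeping locus may still contribute: the 14.8% changed within 5 Mb was reached by 0% of 9575 windows of 962 consecutive tested genes on the other scaffolds, whose highest share was 14.4%. Those windows overlap heavily and stand for few independent regions, so this hypothesis remains open.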

How the results depend on the processing

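Single-position reads, the lane settings, the length offset, the 1 Mb window and the 4-fold and 8-fold minimums were chosen after seeing the data. WEEP kept its direction and its call under all 20 alternatives, with a log2 fold change from -8.32 to -7.87 (adjusted p 2.6e-151 to 5.5e-05), and from -8.32 to -7.87 with a tree left out. The number of changed genes was within 1.5 times of 2131 under RLE and upper-quartile scaling, both filters, limma-voom, single-position reads, both lane settings and the length offset (1611 to 2432). It was 3872 with DESeq2, 710 with a 2-fold minimum and 9 at an adjusted p of 0.01, and from 20 to 3923 with a tree left out; the cause was not tested. Of the 2131 genes, 2129 were also called by DESeq2. The scaffold 3 odds ratio of 1.16 ranged from 1.12 to 5.63 with a tree left out, past the threshold in 3 of 8 fits; it was 1.15 (Fisher exact p = 0.0501) with single-position reads and 1.09 (Fisher exact p = 0.286) within lane 6, the cause not tested, and 16.8 among the 9 genes at an adjusted p of 0.01. It was 1.89 and 3.93 among genes changed at least 4-fold and 8-fold. WEEP counts as a changed gene in all of these odds ratios. The excess within 2 Mb passed neither with all trees nor in any fit with a tree left out (1.12 to 2.30). With all 8 libraries the 5 Mb window gave 1.39 (Fisher exact p = 0.0185) and the 1 Mb window 1.501 (Fisher exact p = 0.0412). Neither of these windows was run with a tree left out or within lane 6. The overlap with the authors' table was 1189 genes with DESeq2 calls. Over 31 other named genes and 20 alternatives, 555 of the values stayed past the threshold and 65 did not, 23 of them at an adjusted p of 0.01, 16 without weeping tree 2 and 11 under the 2-fold minimum, and none changed sign. Pseudocounts apply only to normalized values and were not run, nor were the alternatives for gene lists, which could not be matched. Depth limits WEEP in weeping trees, where 3 to 9 reads set its level.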

Other observations

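Of the 7 genes on scaffold 3 that passed the threshold with an 8-fold or larger fitted change, chosen after their values were seen, 5 lay within 5 Mb of WEEP, WEEP itself included. Of the 1970 tested genes on the scaffold, 962 lie within that distance, so these few genes do not show a gathering there. The gene at 14188940 to 14189764 had 50 to 88 reads in standard and 0 to 5 in weeping trees. The gene at 14133374 to 14134326 went the other way, with 3 to 35 reads in standard and 136 to 225 in weeping trees. The gene at 20891811 to 20894057 had 0 reads in each of the 4 standard trees and 13 to 28 in weeping trees.

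Some genes were switched on or off between single trees whatever their habit. In 40 genes every library was either at most 0.25 or at least 2.5 CPM by unscaled library totals, with both states present. None of the 40 followed habit, but these limits decide that: WEEP itself is left out because some weeping trees exceed 0.25 CPM, and with an upper limit of 0.5 CPM for the off state, 2 of 63 genes followed habit, WEEP among them, both off in weeping trees. On scaffold 2, genes at 456375, 1897574, 4383605 and 13754074 were on in standard tree 8 and weeping tree 1 and off in the other 6 libraries, while the genes at 617006 and 2361009 were on in those 6 and off in both. The other 3 of the 9 such genes on scaffold 2, at 3309169, 5597128 and 5634385, lie between the positions at 456375 and 13754074 and had another pattern: they were off in standard tree 8 alone and on in weeping tree 1, at 3.18 to 13.5 CPM. On scaffold 3 the gene at 14378845 to 14382309 was off in standard trees 8, 9 and 10, at 4.87 CPM in standard tree 7 and at 8.21 to 9.13 in weeping trees.

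Reads shared between gene copies are argued against as the source of the whole set, since the median gene had 97.2% of its reads at a single position, though the lowest had 40.4%. A candidate explanation, formed after the pattern was seen, is that siblings inherited different blocks of parental haplotype. Of 32 neighbouring pairs of these genes on a scaffold, 6 had the same or the mirrored pattern over the 8 trees, against a median of 2 in 10000 shuffles of the patterns (permutation p = 0.0040). Most of these 6 pairs lie on scaffold 2, where the shared pattern was first seen, and without that scaffold 2 of 24 pairs shared it against a median of 1 (permutation p = 0.278), so these genes do not decide the question. With the limit of 0.5 CPM, chosen later still, 8 of 40 pairs outside scaffold 2 shared it against a median of 2 (permutation p = 0.0010). When 1 CPM was also taken as enough for the on state, 22 of 167 such pairs shared it against a median of 12 (permutation p = 0.0024). At 0.25 and 2.5 CPM, the genes of the 2 sharing pairs outside scaffold 2 had 53.8 to 77.6% of their reads at a single position. Reads shared between gene copies could therefore add to such pairs. The result thus depends on the limits, genotypes of the trees were not analysed here, and the explanation stays open.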
